A study of Rattus norvegicus with 18 samples.

How the data were processed

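The values used are RSEM expected counts per gene (estimated counts, fractional because reads that fit several transcripts are shared out) and length-scaled TPM values, both as deposited by the submitters. Per the submitters' processing notes, Trimmomatic, FastQC, STAR 2.7.10b and RSEM 1.3.3 were used with the genome build mRatBN7.2, and the notes do not say what each tool did or in which order. Per the labels, total RNA came from frozen sections of the tibialis anterior, was purified with the RNeasy mini kit and made into libraries with the TruSeq RNA Library Prep Kit Set A, and was sequenced at BGI. The annotation release and the strand setting are not given in the sources used here. Raw reads were not analysed here.

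The count table held 30560 entries for 18 libraries, of which 7162 had no gene symbol. Those without a symbol took 3.64 to 17.6% of the counts of a library. The share was 3.64 to 5.86% in WT at 3 months, 8.25 to 17.1% in WT at 9 months and 8.27 to 10.3% in WT at 18 months. It thus differed between 3 and 18 months, but it did not rise steadily with age and varied widely at 9 months. Of all values 4.50% were not whole, and counts were rounded before the fits. Totals ran from 9.61 M to 15.8 M in WT at 9 months, 11.5 M to 16.6 M in DMD, 10.8 M to 21.99 M in p16-null DMD, 12.3 M to 13.8 M in WT at 3 months and 10.3 M to 12.4 M in WT at 18 months. Gene symbols were taken from the deposited tables. No column of per-sample values was left out.

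Genes with too few counts were removed with filterByExpr, libraries were scaled by TMM, and edgeR 4.0.16 quasi-likelihood tests were run in R 4.3.3. The 3 groups of 9 months shared 1 fit of 14801 genes, and the WT groups of 3 and 18 months another fit of 13487 genes. The biological coefficient of variation was 0.260 in the first fit and 0.176 in the second. P-values were adjusted over all tested genes by Benjamini-Hochberg, and an adjusted p under 0.05 counts as changed. TMM factors were 0.687 to 0.761 in WT at 9 months, 1.07 to 1.19 in DMD and 0.998 to 1.19 in p16-null DMD, so the choice of scaling bears on the directions of change. Where a group held 0 counts of a gene, the fold change is given as a bound against a floor of 3 counts over the group. With 1 to 3 counts it is given as a ratio with a 95% interval.

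A total of 30 gene lists were fixed before the data were examined, and 28 had at least 5 tested members in each comparison. The lists for red blood cells and sex-linked genes had fewer. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, which asks whether the genes of a list rank higher or lower than other genes. Alternatives were camera with a correlation estimated for each list, which allows for genes that vary together, and fry. The fry test asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. List p-values were adjusted over the 28 lists of a comparison. Several list members had no entry under their symbol and are not analysed here.

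Genes named in the text follow a rule. Dmd and Cdkn2a are always given. From each comparison the text gives the 6 largest rises and the 6 largest falls among changed genes with a symbol, a mean log2 CPM of at least 2 and groups that do not overlap. Symbols of unnamed entries, such as those starting with LOC, RGD or AC plus a digit, were left out of these. From each list described, up to 4 members with the smallest p-values are named. A panel of Cdkn1a, Tgfb1, Tgfb2, Inhba, Ccn2, Gdf15, Il6, Spp1, Pax7, Myog, Myh3, Col1a1 and Cd68 is given whether or not it passed. AC239701.1 lies outside the rule. Some results that the rule calls for are not reported here.

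Alternatives were DESeq2 1.42.0 (Wald test), RLE scaling, limma on log2 TPM with a pseudocount of 1 or 0.1, no filter on low counts, and a stricter filter of 5 CPM in 3 libraries. Others were a fit of only the groups compared, 1 fit of all 18 libraries, a robust fit, the 50 most abundant genes left out, the replicate number as a block, a fold change of at least 2, and each library left out in turn. Scaling by library totals was added after results were seen. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

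The steps were tested on simulated data with counts drawn at the depths and spread of these libraries. With 100 genes changed 2-fold and 100 changed 4-fold, 38% and 79% were recovered for DMD against WT (14582 genes), 56% and 91% for p16-null DMD against DMD (14578 genes), 47% and 86% for p16-null DMD against WT (14554 genes) and 67% and 93% for 18 against 3 months (13277 genes). No recovered gene had the wrong direction. Among unchanged genes 8, 6, 7 and 14 were called in these 4 comparisons, and none of the lists left unshifted was called. Each gene was drawn independently, so the simulation could not show list calls that arise when genes vary together. Pairs of replicates differed by more than counting error, with a chi-square per degree of freedom of 11.9 to 79.0 over 27 pairs.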

Results

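RNA of the tibialis anterior, a mostly fast-twitch muscle of the lower hindlimb, was sequenced in 18 libraries from 5 groups of rats. At 9 months of age there were 3 libraries of wild-type (WT) rats, 3 of DMD rats, a model of Duchenne muscular dystrophy, and 6 of DMD rats labelled p16-null. The cell cycle inhibitor p16 is a product of Cdkn2a and a common marker of senescent cells. A further 3 libraries came from WT rats of 3 months and 3 from WT rats of 18 months. Each library held 9.61 M to 21.99 M estimated counts, and p16-null DMD replicate 4 was the deepest. Levels are given below as CPM (normalised counts scaled to a common total) with the SD over n = 3 libraries, or n = 6 for p16-null DMD. Changes are log2 fold changes with an SE derived from the edgeR test, as the size of the change divided by the square root of its F statistic. Nothing beyond the sample titles says that the libraries of a group came from separate rats, so the p-values measure the spread between these libraries, which can be technical in part.

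The targeted genes were examined first. Dmd (ENSRNOG00000046366), which encodes dystrophin, stood at 148 ± 28.0 CPM in WT, 39.1 ± 6.75 in DMD and 45.2 ± 9.53 in p16-null DMD muscle at 9 months, and at 90.2 ± 8.61 and 159.6 ± 26.6 in WT muscle of 3 and 18 months. The fall was 1.92 ± 0.22 on the log2 scale in DMD (adjusted p = 9.6e-06), so the DMD libraries carried the low Dmd level that their label implies. Cdkn2a (ENSRNOG00000059837) was nearly silent in WT muscle, with 0.1121 ± 0.1004 CPM at 9 months, 0 counts at 3 months and 0.170 ± 0.148 CPM at 18 months. It reached 15.1 ± 4.72 CPM in DMD muscle and 13.0 ± 1.73 CPM in the 6 libraries labelled p16-null DMD, which ranged from 10.6 to 15.998 CPM. Cdkn2a counts were 146 times higher in DMD than in WT muscle (95% counting interval 49.8 to 710) and 125 times higher in p16-null DMD than in WT muscle (42.7 to 608). The difference between p16-null DMD and DMD was -0.21 ± 0.23 (adjusted p = 0.98). Gene-level counts pool the p16 and Arf transcripts of Cdkn2a and the labels do not describe the edit, so these values cannot check the p16-null label.

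**Figure D1:**
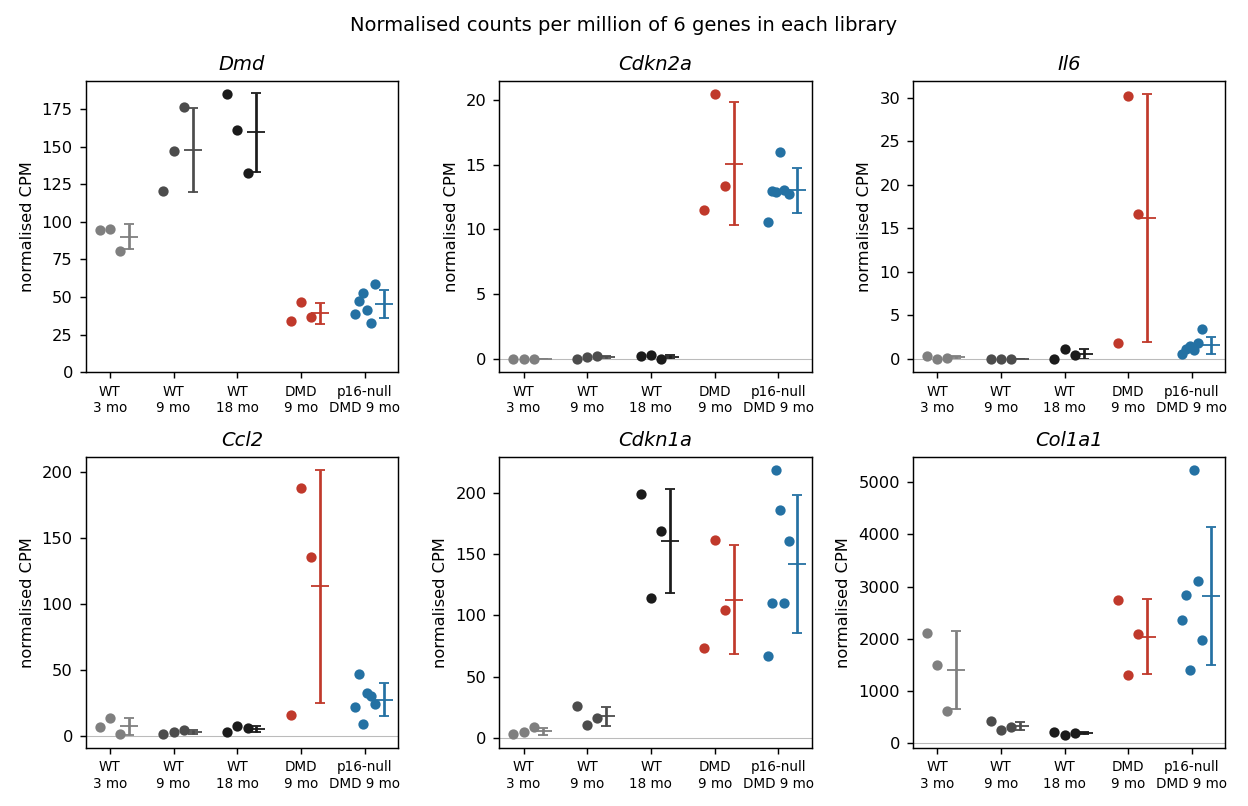
Normalised CPM (y axis, linear) of 6 genes in each library, by group, with the group mean and SD beside the points (n = 3, or 6 for p16-null DMD). Cdkn2a lay between 10.6 and 15.998 CPM in the p16-null DMD libraries, while Il6 ranged from 1.76 to 30.2 CPM over the 3 DMD libraries.

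The comparison of DMD with WT muscle at 9 months asked how the dystrophic muscle differs. Scar matrix, immune cell and complement genes rose together with the genes of regenerating fibres, while the genes of fast fibres, glycolysis and mitochondrial respiration fell. These are list calls by camera with a preset correlation, and none passed with an estimated one (adjusted p = 0.080 to 0.17 with an estimated correlation). Postn, a matrix protein of scar tissue, went from 32.6 ± 13.7 to 371 ± 36.1 CPM, and Myh3, the embryonic myosin heavy chain, from 1.89 ± 1.24 to 229 ± 92.2 CPM. Sdha, a subunit of succinate dehydrogenase, fell from 797 ± 39.6 to 192 ± 39.6 CPM, and Pgm1, which feeds glycogen glucose into glycolysis, from 1911 ± 132 to 392.2 ± 38.4 CPM. Of 14801 genes tested, 7142 changed, 3914 higher and 3228 lower in DMD (edgeR quasi-likelihood test), and 2820 and 1669 of them by at least 2-fold.

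Among matrix genes, 29 of 30 rose (median log2 fold change 2.18, camera adjusted p = 1.0e-18, adjusted p = 0.098 with an estimated correlation), led by Bgn, Mfap4 and Postn at 3.18 ± 0.21, 3.01 ± 0.23 and 3.50 ± 0.29. Fibroblast and fibro-adipogenic progenitor genes such as Pdgfra (1.89 ± 0.26) and Dpt rose in 14 of 18 cases and fell in 1 (median 1.42, adjusted p = 1.5e-05, adjusted p = 0.079 with an estimated correlation). All 23 macrophage genes rose (median 2.59, adjusted p = 1.5e-12, adjusted p = 0.17 with an estimated correlation), among them the lysozyme gene Lyz2 (3.40 ± 0.40), Lgals3 (2.83 ± 0.28) and the mannose receptor Mrc1 (2.59 ± 0.30). All 21 genes of complement and antigen presentation rose (median 1.91, adjusted p = 1.5e-12, adjusted p = 0.080 with an estimated correlation), with Cfb at 2.67 ± 0.21 and C4a at 3.29 ± 0.36. Lymphocyte genes rose in 12 of 14 cases (median 2.75, adjusted p = 0.00028, adjusted p = 0.17 with an estimated correlation). The plasma cell gene Jchain was 129 times higher (43.8 to 626) and the T cell receptor gene Cd3e 77.0 times higher (13.6 to 3064). Of neutrophil and mast cell genes 9 of 11 rose (median 3.21, adjusted p = 0.014, adjusted p = 0.17 with an estimated correlation), with Csf3r at 4.61 ± 0.90 and the neutrophil collagenase Mmp8 61.6 times higher (10.8 to 2456). Of interferon response genes 13 of 22 rose, such as Gbp2 and Dhx58 (median 1.32, adjusted p = 0.0024, adjusted p = 0.52 with an estimated correlation). Adipocyte genes rose in 13 of 18 cases and fell in 1 (median 1.94, adjusted p = 0.00094, adjusted p = 0.45 with an estimated correlation), with the lipid droplet gene Plin1 at 4.27 ± 0.84 and Cfd at 3.86 ± 0.55. Intervals of ratios and floors of 3 counts over a group cover counting error only.

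The muscle fibre programme moved the other way in part. All 12 fast fibre genes fell (median -1.77, adjusted p = 9.2e-07, adjusted p = 0.17 with an estimated correlation), including Ampd1 (-2.42 ± 0.29) and the fast troponin Tnni2 (-1.74 ± 0.28). All 19 genes of glycolysis and glycogen fell (median -2.02, adjusted p = 2.8e-14, adjusted p = 0.17 with an estimated correlation), and Phkg1, a phosphorylase kinase subunit, fell by 3.24 ± 0.36 on the log2 scale. Of genes of oxidative phosphorylation and the TCA cycle 29 of 30 fell (median -1.77, adjusted p = 2.2e-25, adjusted p = 0.12 with an estimated correlation), with Ndufa9 at -1.85 ± 0.19. Atrophy and autophagy genes fell in 12 of 19 cases and rose in 2 (median -0.74, adjusted p = 0.0023, adjusted p = 0.17 with an estimated correlation), among them the ubiquitin ligase genes Fbxo32 and Asb2. Clock genes fell in 8 of 16 cases, with Nr1d1 and Hlf among them (median -0.78, adjusted p = 0.0046, adjusted p = 0.17 with an estimated correlation). Embryonic and regenerating fibre genes rose in 12 of 17 cases and fell in 1 (median 2.59, adjusted p = 2.4e-07, adjusted p = 0.17 with an estimated correlation). They included Myh3, the embryonic light chain Myl4 (2.59 ± 0.23), cardiac actin Actc1 (3.55 ± 0.33) and Tnnt2. Proliferation genes rose in 15 of 25 cases (median 1.74, adjusted p = 0.018, adjusted p = 0.64 with an estimated correlation), with Top2a at 3.53 ± 0.73 and Mki67 at 2.52 ± 0.54, while the spindle gene Tpx2 fell by 3.35 ± 0.50 on the log2 scale.

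Senescence and secretory genes were higher in DMD muscle, as far as their lists go. Of the senescence and cell cycle arrest list 13 of 17 genes rose and 2 fell (median 1.32, adjusted p = 0.00014, adjusted p = 0.080 with an estimated correlation). Beside Cdkn2a these were the inhibitor genes Cdkn2b (2.72 ± 0.35) and Cdkn1a (2.64 ± 0.42) and the lysosomal galactosidase Glb1 (2.07 ± 0.26), whereas Cdkn1b fell by 0.99 ± 0.15 on the log2 scale. Genes of the senescence-associated secretory phenotype (SASP) rose in 25 of 35 cases and fell in 1 (median 2.47, also with the 2 members at 0 counts in a group set to their bound; adjusted p = 1.5e-09, adjusted p = 0.080 with an estimated correlation). Timp1, a protease inhibitor, went from 6.45 ± 1.04 to 184 ± 69.6 CPM, and Mmp2, Csf1 and Cxcl16 rose by 2.29 ± 0.19, 2.18 ± 0.20 and 2.20 ± 0.21. Il6 had 0 counts in WT muscle and was at least 166-fold higher in DMD, with 1.76, 30.2 and 16.6 CPM in DMD replicates 1 to 3. The TGF-beta family list rose in 16 of 30 cases and fell in 4 (median 0.76, adjusted p = 0.0053, adjusted p = 0.17 with an estimated correlation), with Ltbp2 at 3.98 ± 0.38, Tgfbr2 at 1.38 ± 0.15, Tgfb1 at 2.10 ± 0.32 and Ccn2 at 2.06 ± 0.34. Col1a1 (2.64 ± 0.42), Cd68 (3.20 ± 0.48) and Spp1 (5.37 ± 0.91) rose as well. Tgfb2 (0.34 ± 0.34, adjusted p = 0.43), Inhba (0.87 ± 0.65, adjusted p = 0.29) and the satellite cell factor Pax7 (-0.18 ± 0.44, adjusted p = 0.77) did not pass by edgeR. Tgfb2 did pass by library totals (0.97, adjusted p = 0.027) and with TPM (1.03, adjusted p = 0.016), and Inhba with TPM (0.82, adjusted p = 0.034). Gdf15 (1.65 ± 0.68, adjusted p = 0.058) did not pass either, but did without WT replicate 3 (adjusted p = 0.0434) or p16-null DMD replicate 6 (adjusted p = 0.046). It also passed by DESeq2 (adjusted p = 0.023), by library totals (0.010) and with TPM (0.0020). Myogenin, Myog, was at 1.11 ± 0.46 (adjusted p = 0.058) and passed without DMD replicate 1 (adjusted p = 0.019), p16-null DMD replicate 1 (adjusted p = 0.032) or replicate 6 (adjusted p = 0.047). It passed as well by library totals (1.74, adjusted p = 0.0046), with TPM (1.72, adjusted p = 0.0058), without a filter (adjusted p = 0.039), in a fit of only the groups compared (0.033) and in a fit of 18 libraries (0.032).

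**Figure D2:**
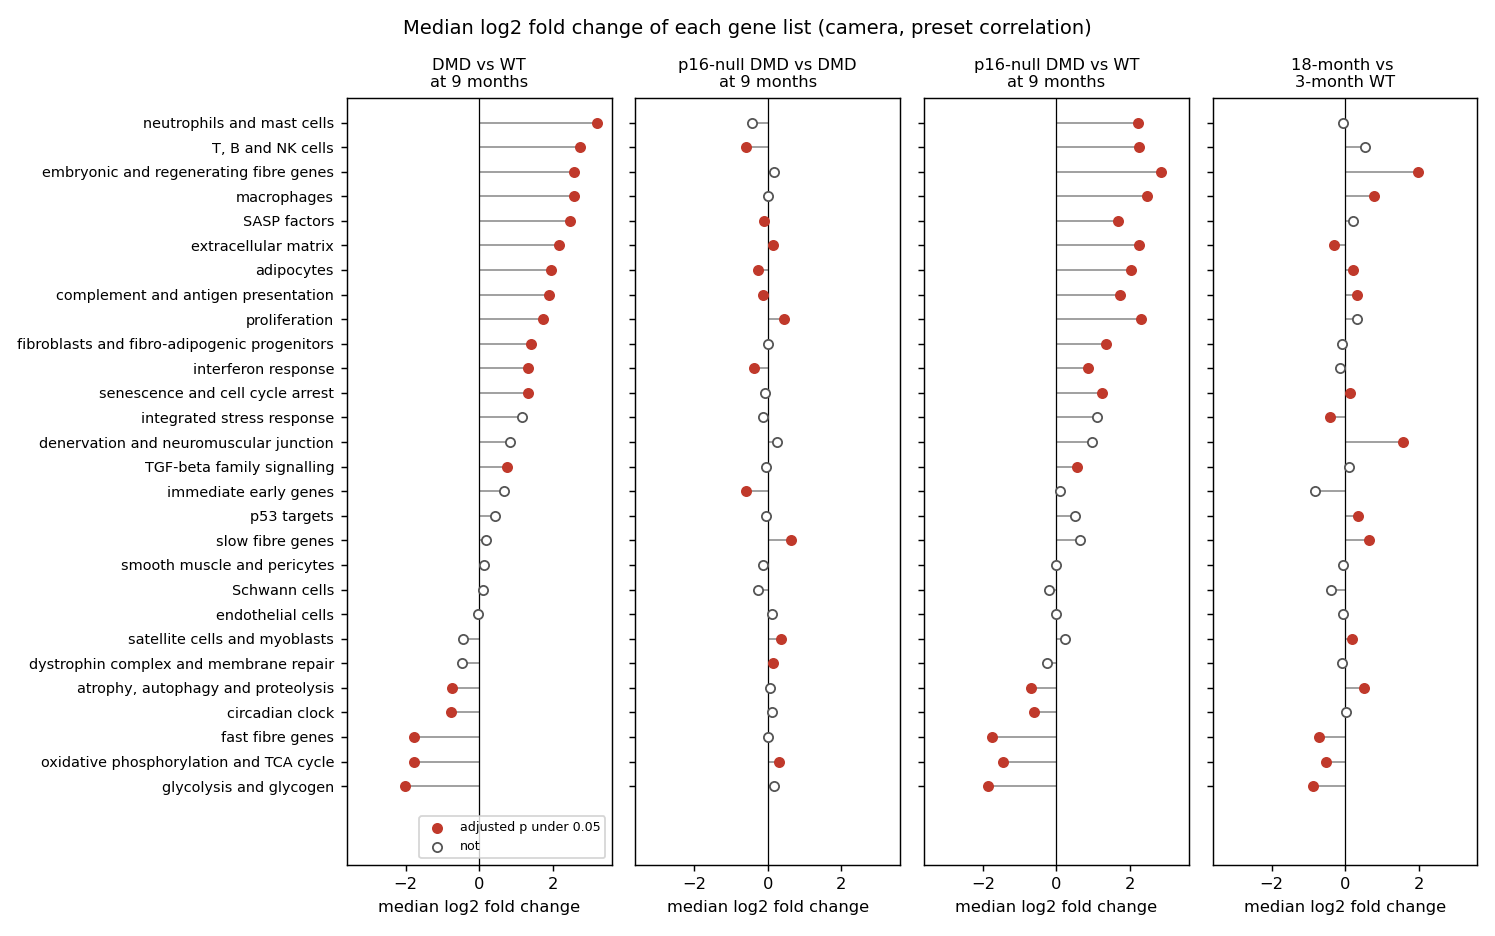
Median log2 fold change (x axis) of 28 gene lists in 4 comparisons; filled points passed the camera test with a preset correlation and open points did not. The lists for fast fibres, oxidative phosphorylation and glycolysis lie at -1.77, -1.77 and -2.02 in DMD against WT, and no list passed in the 9-month comparisons with an estimated correlation.

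By camera the other lists did not shift as a whole in DMD against WT, though members changed. By fry 3 of them moved, p53 targets up (adjusted p = 0.0073), the stress response up (0.00020) and the dystrophin complex down (0.00043). Satellite cell and myoblast genes split, with 3 of 17 higher and 6 lower (adjusted p = 0.85; median -0.44, mean 0.23). The fusion gene Mymk rose by 4.18 ± 0.64 and Myf5 by 2.43 ± 0.40, while Myod1 fell by 1.06 ± 0.36 on the log2 scale (adjusted p = 0.022). The Myod1 call was lost without WT replicate 1 (adjusted p = 0.11) or 3 (0.065) and without DMD replicate 1 (0.086) or 3 (0.056). Endothelial genes were lower in 3 of 14 cases and higher in none (median -0.04, adjusted p = 0.49), with the water channel Aqp1 at -1.11 ± 0.22. Cdh5, another endothelial gene, was at -0.64 ± 0.19 (adjusted p = 0.014) and at 0.03 when scaled by library totals, and its call was lost without WT replicate 1 (adjusted p = 0.052) or 2 (0.057) or DMD replicate 2 (0.063). Among slow fibre genes 3 of 12 rose and 1 fell (adjusted p = 0.60), with Casq2 at 3.57 ± 0.38 and Myl3 at -2.70 ± 0.61. Of p53 targets 5 of 15 rose, Pmaip1 among them, and 4 fell, Sesn1 among them (adjusted p = 0.53). Denervation and neuromuscular junction genes rose in 7 of 19 cases, such as Runx1, and fell in 2 (adjusted p = 0.29). Dystrophin complex and repair genes fell in 12 of 23 cases, with the sarcoglycan gene Sgcb at -1.67 ± 0.15, and rose in 6 (adjusted p = 0.093). The annexins Anxa1 and Anxa2 stood at 1.92 ± 0.19 and 1.997 ± 0.22. Stress response genes rose in 7 of 17 cases, including Asns, and fell in 2 (adjusted p = 0.17), and immediate early genes rose in 7 of 20 and fell in 2 (adjusted p = 0.45). Schwann cell genes rose in 5 of 12 cases (adjusted p = 0.32), and smooth muscle and pericyte genes rose in 2 of 14 and fell in 3 (adjusted p = 0.67; median 0.14, mean -0.08). The haemoglobin genes Hba-a2 and Hbb-b1, of a list too short for a list test, fell by 2.37 ± 0.27 and 2.84 ± 0.31 on the log2 scale, and neither of the 2 tested sex-linked genes passed.

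By fitted log2 fold change the 6 highest genes in DMD muscle under the naming rule were Il6 and 5 others with 0 to 2 counts over the WT libraries. The tenascin gene Tnn was at least 153-fold higher, Ptprv at least 91.3-fold, Clec2dl1 at least 61.2-fold and the macrophage gene Cd5l at least 40.6-fold, and the phosphate hormone Fgf23 was 727 times higher (201 to 6006). Such bounds and ratios do not rank these genes above others with few WT counts, such as Sohlh2, 470 times higher (84.1 to 18580). The lowest by the same measure were Barx2, 388 times lower (107 to 3214), the water channel Aqp4, from 199.8 ± 10.4 to 2.61 ± 1.59 CPM, Cd24 (-4.67 ± 0.65), Unc5a (-4.60 ± 0.54), Cacng7 (-4.35 ± 0.50) and Chac1 (-4.92 ± 0.72). Each library of 1 group lay beyond each of the other for these genes. The 50 most abundant genes took 48.7 ± 1.89% of counts in WT and 31.6 ± 2.12% in DMD muscle. The median gene stood 0.11 higher in DMD on the log2 scale after TMM scaling but 0.76 higher by library totals. By library totals 8931 genes changed, 7691 higher and 1240 lower. With deposited TPM 8924 changed, 7879 higher and 1045 lower, so directions here are relative to the TMM scale. Adjusted over the list alone, counts of genes higher and lower became 28 and 1 for SASP, 6 and 4 for p53 targets, 13 and 0 for lymphocytes, 4 and 6 for satellite cells, 14 and 1 for embryonic fibres, 3 and 13 for atrophy, 8 and 2 for the stress response and 0 and 10 for the clock, and were unchanged for the other lists.

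The comparison of p16-null DMD with DMD muscle asked what loss of p16 alters in the dystrophic muscle. Almost no gene separated the 6 libraries labelled p16-null DMD from the 3 DMD libraries. The inflammatory cytokine Il6 and the monocyte chemokines Ccl2 and Ccl7 had lower means in p16-null DMD, but the DMD libraries differed widely among themselves. Il6 averaged 16.2 ± 14.2 CPM in DMD and 1.52 ± 1.01 in p16-null DMD (-3.41 ± 0.64, adjusted p = 0.28). Ccl2 stood at 16.2, 188 and 136 CPM in DMD replicates 1 to 3 and at 27.7 ± 12.5 in p16-null DMD (-2.04 ± 0.51, adjusted p = 0.43), and Ccl7 at -2.37 ± 0.54 (adjusted p = 0.35).

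Of 14801 genes 1 changed by edgeR, 12 by DESeq2 (2 higher, 10 lower) and 2 by limma on TPM, and 764 had an unadjusted p under 0.05 where 740 would by chance. The 1 gene, AC239701.1 (ENSRNOG00000060437), was chosen after its values were seen, since the naming rule left out symbols of this unnamed type. It had 1 count over the 6 p16-null DMD libraries and 350 over the 3 DMD libraries, 682 times lower (122 to 27023; adjusted p = 4.7e-07). With the replicate number as a block it did not pass by edgeR (-9.725, adjusted p = 0.064). Without DMD replicate 1, however, 85 genes changed, 5 higher and 80 lower, among them Il6 (-3.94, adjusted p = 0.0057), Ccl7 (-2.88, 0.0079), Ccl2 (-2.55, 0.0079), Nr4a3 (-2.12, 0.0079), Fosl2 (-1.26, 0.019), Ifit3 (-1.62, 0.025) and Csf1 (-0.84, 0.026). Without DMD replicate 3 or p16-null DMD replicate 2 the count was 2. The other genes followed for each comparison did not pass, with Cdkn1a at 0.33 ± 0.34, Tgfb1 at -0.04 ± 0.25 and Tgfb2 at -0.04 ± 0.29. Inhba was at -0.49 ± 0.52, Ccn2 at 0.34 ± 0.28, Gdf15 at -0.05 ± 0.54, Spp1 at 1.72 ± 0.67 and Cd68 at 0.26 ± 0.36. Col1a1 was at 0.47 ± 0.35, Pax7 at 0.69 ± 0.38, Myog at 0.59 ± 0.40, Myh3 at 0.18 ± 0.32 and Dmd at 0.21 ± 0.19, with adjusted p from 0.83 to 0.99 over these 13 genes.

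By camera with its preset correlation 12 of 28 lists shifted in p16-null DMD against DMD, 6 higher and 6 lower, but none did with an estimated correlation, none by fry, and no member of a list passed over all genes. SASP genes lay lower as a list (median -0.09, mean -0.48, adjusted p = 5.4e-06, adjusted p = 0.30 with an estimated correlation), with 7 of 35 lower when adjusted over the list alone. The typical member thus hardly moved, and a part of the list carried the shift. Immediate early genes such as Fosl2 (-0.94 ± 0.26), Nr4a3 (-1.62 ± 0.46) and Egr3 (-1.40 ± 0.44) lay lower as well (median -0.59, adjusted p = 6.3e-07, adjusted p = 0.41 with an estimated correlation), 3 of 20 when adjusted over the list alone. Lymphocyte genes, with Cd3g at -1.30 ± 0.63, had a median of -0.60 (adjusted p = 5.8e-05, adjusted p = 0.30 with an estimated correlation). Genes of oxidative phosphorylation lay higher (median 0.31, adjusted p = 1.5e-09, adjusted p = 0.48 with an estimated correlation), with Ndufa9 at 0.43 ± 0.16 and Fh at 0.40 ± 0.15. These 4 lists passed with any single library left out, which cannot remove DMD replicates 2 and 3 together. Immediate early genes had a mean log2(CPM + 1) of 6.10 and 5.89 in those. DMD replicate 1, at 4.69, lay below all p16-null DMD libraries (4.83 to 5.29). The other 8 lists were lost or turned without at least 1 library. Lower were interferon response genes (median -0.38, adjusted p = 0.00016, adjusted p = 0.54 with an estimated correlation), with Ifit3 at -1.28 ± 0.32 and Ifit2 at -0.77 ± 0.23, where 1 was lower adjusted over the list alone. Also lower were adipocyte genes (median -0.26, adjusted p = 0.0019, adjusted p = 0.56 with an estimated correlation) and complement and antigen presentation genes (median -0.12, adjusted p = 0.041, adjusted p = 0.56 with an estimated correlation). Slow fibre genes lay higher (median 0.63, adjusted p = 0.00019, adjusted p = 0.54 with an estimated correlation), with Myl3 at 1.298 ± 0.53 and Tnni1 at 0.80 ± 0.36. So did satellite cell genes (median 0.36, adjusted p = 0.00055, adjusted p = 0.41 with an estimated correlation), proliferation genes (0.43, adjusted p = 0.0021, adjusted p = 0.56 with an estimated correlation), matrix genes (0.14, adjusted p = 0.014, adjusted p = 0.57 with an estimated correlation) and dystrophin complex genes (0.13, adjusted p = 0.019, adjusted p = 0.30 with an estimated correlation). Calls ended without DMD replicate 1 for satellite cells and proliferation, without DMD replicate 2 for matrix (median 0.03) and proliferation, and without DMD replicate 3 for slow fibres, dystrophin complex, interferon (median 0.01) and complement (median 0.04), with adjusted p up to 0.90. They ended without p16-null DMD replicate 1 for adipocytes and proliferation, replicate 2 for matrix, replicates 3 and 6 for complement, and replicate 4 for matrix, adipocytes and dystrophin complex. Senescence and cell cycle arrest genes had a median of -0.06 (adjusted p = 0.20), with 1 lower adjusted over the list alone. TGF-beta family genes had a median of -0.04 (adjusted p = 0.060), with 2 lower adjusted over the list alone, and macrophage genes of -0.0043 (adjusted p = 0.41, with a mean of 0.035).

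The comparison of p16-null DMD with WT muscle asked how much of the dystrophic difference was seen in the p16-null libraries. It showed the pattern of DMD against WT. Matrix, macrophage and embryonic fibre genes were higher and metabolic and fast fibre genes lower than in WT muscle, none of these lists with an estimated correlation (adjusted p = 0.078 to 0.21 with an estimated correlation). Bgn stood at 3.16 ± 0.20, Lgals3 at 2.84 ± 0.26, Myh3 at 7.05 ± 0.49, Sdha at -1.71 ± 0.15 and Phkg1 at -2.80 ± 0.28. Cdkn1a rose from 18.0 ± 7.73 to 142 ± 56.2 CPM and Spp1 from 3.43 ± 0.646 to 476 ± 446 CPM. Of 14801 genes 7432 changed, 4073 higher and 3359 lower, and 18 lists shifted, 13 higher and 5 lower, none of them with an estimated correlation (lowest adjusted p = 0.078 with an estimated correlation, shared by several lists). Scaled by library totals 9322 changed, 8071 higher and 1251 lower, and with TPM 9555 changed, 8579 higher and 976 lower.

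Both sets of muscle against WT shared 3496 genes that were higher and 2938 that were lower, and none changed in opposite directions. Independent calls would share 1077.1 and 732.6. In 20 simulations with the DMD effects but none of p16 loss, 3563.6 (at least 3499) and 3148.3 (at least 3102) were shared on average. The observed counts lay below both ranges. Genes vary independently in these simulations and shifts of whole libraries were not modelled, so the ranges may be too narrow. The simulated p16-null libraries were also given the observed DMD rates. Chance deviations of the DMD libraries thus counted as effects, which can raise the shared counts. The ranges therefore show no effect of p16 loss. Part of the excess over independent calls may come from the shared WT libraries, and the 3 of them cannot be divided to leave at least 2 for each contrast. Over genes the covariance of the log2 fold changes was 1.86, against 0.0894 in simulated groups with no effect that share the WT libraries, a difference of 1.77. The SASP list was higher, with 26 of 35 genes up and 1 down (median 1.68, adjusted p = 1.0e-07, adjusted p = 0.078 with an estimated correlation; 27 and 1 adjusted over the list alone). Mmp2 (2.23 ± 0.18) and Timp1 (4.21 ± 0.41) were among them, and Il6 was at least 14.0-fold higher. Gdf15 rose by 1.60 ± 0.63 (adjusted p = 0.044), which ended without any single library except WT replicate 3 or p16-null DMD replicates 4 and 6 (adjusted p up to 0.10). Satellite cell genes rose in 5 of 17 cases and fell in 2 (adjusted p = 0.50), with Mymk at 4.80 ± 0.62 and Myog at 1.71 ± 0.43, and Pax7 was at 0.51 ± 0.39 (adjusted p = 0.29). Tgfb2 (0.31 ± 0.30) and Inhba (0.38 ± 0.58) did not pass. By library totals and with TPM, Pax7 (1.11, adjusted p = 0.022, and 0.80, 0.015) and Tgfb2 (0.93, adjusted p = 0.019, and 0.95, 0.011) did pass. The list for interferon response (median 0.85, adjusted p = 0.022, adjusted p = 0.59 with an estimated correlation) was lost without WT replicate 3 (adjusted p = 0.089). By fitted log2 fold change the highest under the naming rule were Tnn (at least 269-fold), Clec2dl1 (at least 93.4-fold), Ptprv (at least 81.4-fold), Gdf5 (at least 57.0-fold), Mmp12 (at least 54.1-fold) and Cd5l (at least 50.01-fold), though Sohlh2, 612 times higher (110 to 24167), is not ranked by such bounds. The lowest were Barx2 (-7.47 ± 0.72), Aqp4 (-5.22 ± 0.54), Unc5a (-4.70 ± 0.42), Mettl11b (-4.47 ± 0.62), Cd24 (-3.97 ± 0.48) and Adcy1 (-3.87 ± 0.25).

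Genes that changed in DMD and moved back in p16-null DMD would mark a reversal. None passed both tests by edgeR, where 0.264 would by chance from the 1 gene called lower. By DESeq2 there were 9, 8 of them higher in DMD, and without DMD replicate 1 there were 80, 75 of them higher in DMD. At an unadjusted p under 0.05 in the second contrast, 509 genes changed in DMD had moved back and 29 further away. In 20 simulations with the DMD effects but none of p16 loss these averaged 282.2 (265 to 331) and 131.95 (112 to 145), and the observed counts lay outside both ranges. In the simulations genes vary independently, and a library that shifts many genes at once was not modelled. The simulated p16-null libraries again had the observed DMD rates, with the chance deviations of the DMD libraries in them. The DMD libraries enter both contrasts with opposite signs, which alone gave a covariance of -0.0804 over genes in simulated groups with no effect. The observed value was -0.184, a difference of -0.104. The correlation over genes was r = -0.332, against -0.563 on average in those groups. Those groups hold no DMD difference, which changes the scale of r, so these values of r are not comparable. In the simulations with the DMD effects r averaged -0.140 (-0.163 to -0.121) and the covariance -0.0726 (-0.0869 to -0.0623). Both observed values were more negative, under the limits of these simulations given above.

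The comparison of WT muscle at 18 and 3 months asked what age changes in healthy muscle. The older muscle carried a strong denervation and myogenic programme. Ankrd1 went from 7.12 ± 2.48 to 697 ± 72.4 CPM and the myogenic factor Myog from 8.36 ± 2.84 to 193.8 ± 21.8. Cdkn1a, the main p53 target that arrests the cell cycle, rose from 5.79 ± 2.83 to 161 ± 42.7 CPM. The haemoglobin gene Hba-a2 fell by 2.40 ± 0.23 on the log2 scale, and the collagen genes Col1a1 and Col3a1 by 2.87 ± 0.32 and 1.59 ± 0.17. Of 13487 genes tested, 2622 changed, 1256 higher and 1366 lower, and 1696 did without the 18-month replicate 1.

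Denervation and neuromuscular junction genes rose in 13 of 19 cases and fell in 2 (median 1.56, adjusted p = 6.0e-43, adjusted p = 0.011 with an estimated correlation), with Ncam1 at 4.60 ± 0.15 and the synaptic kinase Musk at 4.22 ± 0.21. Embryonic and regenerating fibre genes rose in 14 of 16 cases (median 1.98, adjusted p = 4.3e-57, adjusted p = 0.011 with an estimated correlation), Myh3 by 3.79 ± 0.27, and adjusted over the list alone 15 rose and 1 fell. Satellite cell and myoblast genes rose in 7 of 18 cases (median 0.20, adjusted p = 2.2e-13, adjusted p = 0.011 with an estimated correlation). Those were fusion and differentiation genes such as Mymx (6.85 ± 0.43) and Mymk (5.44 ± 0.41), while Pax7 was at -0.17 ± 0.58 (adjusted p = 0.88). Several genes belong to more than 1 of these 3 lists, Myog and Ncam1 among them. Senescence and cell cycle arrest genes rose in 4 of 16 cases and fell in 1 (median 0.14, adjusted p = 0.0033, adjusted p = 0.11 with an estimated correlation). Beside Cdkn1a (4.80 ± 0.29) these included Cdkn2b (4.95 ± 0.34) and Uchl1 (3.24 ± 0.51). Of p53 targets 4 of 15 rose and 2 fell (median 0.36, adjusted p = 0.00097, adjusted p = 0.11 with an estimated correlation), with Gadd45a at 3.79 ± 0.25 and Phlda3 at 1.28 ± 0.16, and 5 and 2 adjusted over the list alone. Cdkn1a belongs to both the senescence and the p53 list, and Gadd45a to both the p53 and the denervation list. The shifts of these lists are therefore not independent. Macrophage genes rose in 15 of 23 cases (median 0.78, adjusted p = 6.9e-08, adjusted p = 0.33 with an estimated correlation; 16 adjusted over the list alone), with Gpnmb at 2.75 ± 0.23 and Lgals3 at 0.91 ± 0.17. Complement and antigen presentation genes rose in 8 of 21 cases (median 0.33, adjusted p = 0.00017, adjusted p = 0.23 with an estimated correlation; 9 adjusted over the list alone), B2m by 1.02 ± 0.13.

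Fast fibre genes fell in 10 of 12 cases (median -0.71, adjusted p = 5.9e-09, adjusted p = 0.11 with an estimated correlation; 11 adjusted over the list alone), with Casq1 at -1.23 ± 0.15 and Actn3 at -1.22 ± 0.16 (adjusted p = 0.13 in a fit of 18 libraries). Genes of glycolysis and glycogen fell in 16 of 19 cases and rose in 1 (median -0.87, adjusted p = 1.4e-13, adjusted p = 0.23 with an estimated correlation; 18 and 1 adjusted over the list alone), with Gpd1 at -1.40 ± 0.14. Respiratory and TCA cycle genes fell in 19 of 30 cases (median -0.52, adjusted p = 2.0e-09, adjusted p = 0.38 with an estimated correlation; 26 adjusted over the list alone), with Cycs at -1.16 ± 0.13 and Ndufv2 at -0.80 ± 0.13. Atrophy and autophagy genes rose in 9 of 19 cases and fell in 1 (median 0.52, adjusted p = 0.00018, adjusted p = 0.087 with an estimated correlation; 11 and 2 adjusted over the list alone), with the cathepsin gene Ctsl at 1.90 ± 0.17, Fbxo32 at 1.22 ± 0.14 and Sqstm1 at 1.01 ± 0.13. Slow fibre genes rose in 4 of 12 cases, Myom3 by 3.73 ± 0.25 (list adjusted p = 0.049, adjusted p = 0.64 with an estimated correlation). Adipocyte genes rose in 4 of 18, Thrsp by 1.85 ± 0.19, with 1 lower (list adjusted p = 0.049, adjusted p = 0.49 with an estimated correlation). Stress response genes fell in 3 of 15, Atf4 by 0.81 ± 0.15 on the log2 scale (list adjusted p = 0.049, adjusted p = 0.23 with an estimated correlation; 4 adjusted over the list alone). Matrix genes fell in 10 of 30 cases and rose in 4, Fbln1 among those at 1.45 ± 0.17 (median -0.31, adjusted p = 0.027, adjusted p = 0.71 with an estimated correlation; 12 and 4 adjusted over the list alone). Each of these last 4 lists was lost without 1 or more single libraries. Those were for slow fibres the 3-month replicate 1 or 2 or the 18-month replicate 3 (median -0.29), and for adipocytes the 3-month replicate 2 or the 18-month replicate 2 or 3. For the stress response they were the 3-month replicate 1 or 2 or the 18-month replicate 2, and for matrix the 3-month replicate 1 or the 18-month replicate 2 or 3. SASP (5 of 25 higher, 5 lower, adjusted p = 0.29) and TGF-beta family genes (6 of 30 higher, 4 lower, adjusted p = 0.67) did not shift as lists. Igfbp5, Angptl4 and Timp1 still rose by 1.42 ± 0.18, 3.00 ± 0.45 and 1.46 ± 0.24, Spp1 by 2.90 ± 0.48 (adjusted p = 0.086 in a robust fit), Fst by 1.38 ± 0.23, and Mstn fell by 1.73 ± 0.29 on the log2 scale.

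Among the largest fitted changes with age, Krt18 was 358 times higher (63.8 to 14176) and Sohlh2 289 times higher (51.5 to 11450) at 18 months, and Prrt4 rose by 7.62 ± 0.40. The largest falls under the naming rule were in the tendon and cartilage genes Cilp2 (-5.16 ± 0.71), Chad (-4.61 ± 0.77), Col11a2 (-4.40 ± 0.57), Tnmd (-4.18 ± 0.61), Kera (-3.40 ± 0.54) and Fmod (-2.91 ± 0.46). Their level at 3 months varied widely between libraries, for Fmod from 50.7 to 328 CPM. The calls of Cilp2, Chad, Tnmd, Kera and Fmod ended in a robust fit (adjusted p = 0.062 to 0.098). Col1a1 stood at 2103, 1497 and 611 CPM in 3-month replicates 1 to 3 and at 192 ± 27.5 CPM at 18 months. Tgfb2 (0.85 ± 0.22), Tgfb1 (0.67 ± 0.18), Ccn2 (0.61 ± 0.17) and Cd68 (1.03 ± 0.24) rose, calls that each ended without at least 1 library. Those were the 18-month replicate 1 for Tgfb2 (adjusted p = 0.054), Tgfb1 (0.081) and Ccn2 (0.10), the 18-month replicate 2 for Ccn2 (0.13) and Cd68 (0.051), the 3-month replicate 1 for Ccn2 (0.081) and the 3-month replicate 2 for Tgfb1 (0.065) and Ccn2 (0.050). Inhba (-0.21 ± 0.57) did not pass. Cdkn2a, Il6 and Gdf15 had too few counts to be tested, and Dmd rose by 0.82 ± 0.14 (adjusted p = 0.00094). Scaled by library totals the median gene stood 0.24 higher at 18 months, and 2609 genes were then higher and 652 lower.

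The overlap of both lists asked whether dystrophy and age change the same genes. Myh3, Cdkn1a, Cdkn2b and Mymk rose in both, while Phkg1, Hba-a2 and Hbb-b1 fell in both. Of 13428 genes tested in both fits, which share no library, 559 were higher in both, where 316.7 would be by chance (odds ratio 2.66, 95% interval 2.35 to 3.00, Fisher's exact test p = 2.8e-55). Another 962 were lower in both against 327.0 by chance (odds ratio 10.4, interval 9.16 to 11.8). Opposite changes were fewer than by chance, with 108 genes higher in DMD and lower at 18 months (odds ratio 0.229) and 133 the other way (0.351). Col1a1 and Dmd were among these. Genes are not independent replicates, so Fisher's p and the intervals of the odds ratios do not measure the spread between libraries. With the same limit, the 2 sets of log2 fold changes correlated over genes at r = 0.415 and rho = 0.388. The higher and lower parts were 2028 and 257 genes with TPM, and 1807 and 377 by library totals.

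**Figure D3:**
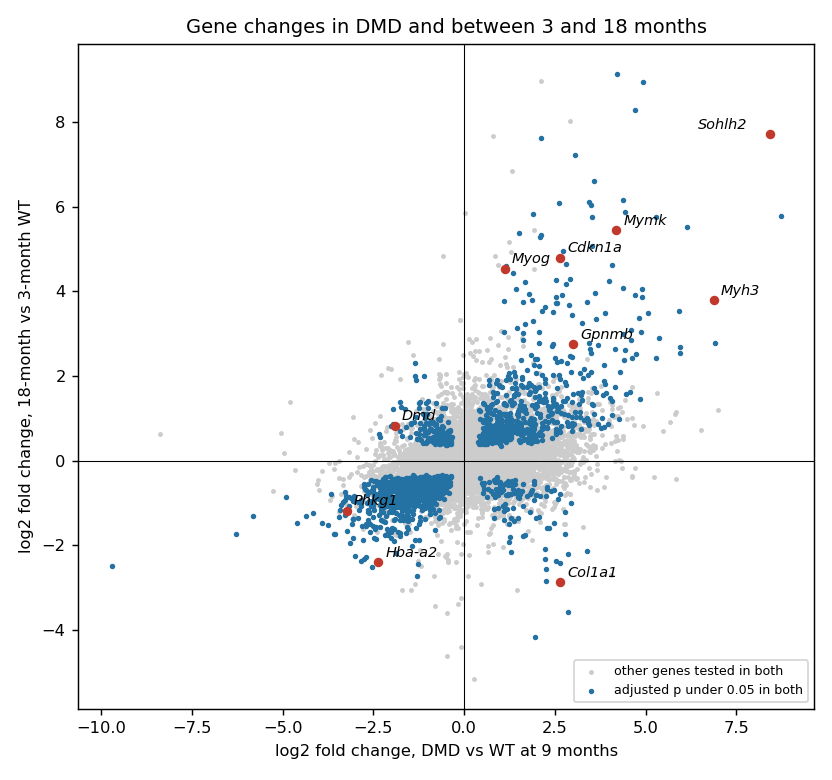
Log2 fold change of each gene in DMD against WT at 9 months (x axis) and in WT at 18 against 3 months (y axis), with genes past the threshold in both in blue, others in grey and named genes in red whether or not they passed in both. Mymk (4.18 and 5.44) and Cdkn1a (2.64 and 4.80) lie at the upper right, while Col1a1 (2.64 and -2.87) and Dmd (-1.92 and 0.82) lie in opposite directions.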

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

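The splits of libraries in this part were planned, while the tests of AC239701.1, the cytokines and tendon were chosen only after the result was seen.

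A test for single extreme libraries looked at 61 values in the 6 p16-null DMD libraries, and by chance about 1 in 20 values would be marked. It marked 5. Inhba (Dixon ratio 0.668) was high in replicate 4, with 2.23 CPM against 1.07 for the next library. AC239701.1 (ratio 1) had 0.0456 CPM in replicate 4 and 0 elsewhere, which is a single count. Nr4a3 (ratio 0.629) was low in replicate 1, with 4.30 against 12.6 CPM. Adcy1 (ratio 0.687) was high in replicate 5, with 6.47 against 4.22 CPM. The total count (ratio 0.682) was high in replicate 4, with 21.99 M against 14.4 M.

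The libraries were also divided anew into groups of the same sizes. For p16-null DMD against WT, 1 of 84 splits, the real one, called as many as 7432 genes and the highest other called 44. Each other split mixes WT with p16-null DMD libraries in a group. The difference between them then widens the spread, so few calls follow by design. The low counts thus do not measure chance, and the splits show only that the real groups ranked first. For its 18 shifted lists, 5 of 84 splits gave as many and the highest other gave 19. The mixed splits still hold the WT libraries, so their list calls need not be chance, and the splits cannot decide here. For p16-null DMD against DMD chance is not excluded, neither for genes (9 of 84 splits gave at least 1 gene, the highest other 242) nor for lists (31 of 84 gave at least 12, the highest other 18). The split that calls 242 genes sets p16-null DMD replicates 1, 4 and 5 apart. It was picked as the highest of the splits, so it does not by itself show a structure of these samples, which was not tested. The groups of 3 allow only 10 splits, too few to exclude chance. For DMD against WT the real count was 7142 genes and the highest other 1, with 1 split as high as the real one, and for lists 18 against 20, with 2 splits. For age the values were 2622 genes and 0, with 1 split, and 15 lists and 12, with 1 split.

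AC239701.1 was all but absent from the 6 p16-null DMD libraries. At the rate of the DMD libraries 682.2 counts would be found there, so low depth is excluded. Outside the group 1 library, WT 3-month replicate 1, also had 0 counts, so a DNA difference carried by the p16-null line or shared by related rats cannot be told from an effect of p16 loss.

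Il6, Ccl2 and Ccl7 had lower means in p16-null DMD than in DMD, though DMD replicate 1 was as low as the p16-null libraries. The median change of macrophage genes was -0.00427 with an interquartile range of 0.423, against -2.04 for Ccl2. This argues against a smaller share of macrophages as a whole. A smaller share of some macrophages or of another source cell was not tested, nor were macrophage genes compared library by library. Stress of the tissue before freezing could not be told apart. Over the 6 p16-null DMD libraries immediate early genes and the 3 cytokines correlated at r = -0.449 (exact permutation p = 0.364). Without the 2 libraries farthest from the median r was 0.863, a value of 4 libraries that decides nothing. In DMD replicates 1 to 3 the mean log2(CPM + 1) was 4.69, 6.10 and 5.89 for immediate early genes and 3.19, 6.71 and 6.04 for the cytokines. Both were thus higher in replicates 2 and 3. Loss of p16 itself could not be judged, as 85 genes changed without DMD replicate 1 but 1 or 2 without another DMD library.

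Tendon genes were lower at 18 than at 3 months, and extra tendon in 3-month replicates 1 and 2 may be part of the cause. Of 17 tested tendon markers 58.8% were lower at 18 months, while Scx (adjusted p = 0.038) and Prg4 (adjusted p = 0.0098) were higher, which leaves this open. The 6 genes that prompted the test are among these markers, and of the other 11 only 4 were lower. A fall of collagen synthesis after growth has ended was not tested.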

How the results depend on the processing

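Scaling by library totals was chosen only after the result was seen, and the other alternatives were planned. Alternatives without the DMD libraries highest in Il6, and without the 3-month libraries highest in tendon genes, were tried and removed, since they pick libraries by the outcome. The latter also left 1 library in its group.

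At a fold change of at least 2, 4489 genes changed in DMD against WT, 4221 in p16-null DMD against WT, 802 with age and 407 in both DMD and age. For p16-null DMD against DMD DESeq2 called 12 genes and limma on TPM 2 with either pseudocount. With each library left out that count ran from 1 to 85, and the age count from 1696 to 2415. The age count was 1742 in the fit of 18 libraries. Genes that moved back numbered 9 by DESeq2, 2 and 1 by limma on TPM (pseudocount 1 and 0.1), 1 by library totals, and 0 to 80 with each library left out, the highest without DMD replicate 1. Genes changed in both DMD and age numbered 2285 with TPM. With an estimated correlation 0, 0, 0 and 3 lists passed in the 4 comparisons. By fry 21, 0, 22 and 15 did.

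Titles give groups the same replicate numbers, and a replicate block treats these as pairs. Same numbers correlated at -0.207 to 0.108, and only some libraries matched their own number best, so nothing shows that the numbers are pairs. With the replicate block 6476, 0, 6100 and 2906 genes changed, and for p16-null DMD against DMD 6 lists shifted. In that comparison the camera calls of matrix (adjusted p = 0.42), adipocytes (0.094), satellite cells (0.40) and dystrophin complex (0.070) ended. So did those of proliferation (0.40), interferon response (0.50) and complement (0.48). Signs turned for Tgfb2 (0.053) and Gdf15 (0.071) in p16-null DMD against DMD and for Inhba (-0.14) in p16-null DMD against WT. AC239701.1 did not pass (adjusted p = 0.064), nor did Myod1 in DMD against WT (-1.08, adjusted p = 0.055), Gdf15 in p16-null DMD against WT (1.87, adjusted p = 0.069), or with age slow fibre and stress response genes as lists (adjusted p = 0.066 each).

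Some genes that did not pass changed sign. In DMD against WT, Pax7 was at 0.34 and 0.51 with TPM and 0.49 by library totals, and at -0.53 to 0.054 with each library left out, while Tgfb2 ranged from -0.00020 to 0.52 with each library left out and up to 1.08 over all alternatives. Cdh5, which had passed, was at 0.081 and 0.082 with TPM and 0.026 by library totals. In p16-null DMD against DMD ranges with each library left out were -0.37 to 0.072 for Cdkn2a, -0.29 to 0.31 for Tgfb2, -0.22 to 0.11 for Gdf15, -0.22 to 0.21 for Tgfb1 and -0.023 to 0.55 for Myh3. In p16-null DMD against WT Inhba ranged from -0.029 to 0.66 with each library left out and from -0.14 to 0.94 over all alternatives. With age Inhba was at 0.057 and 0.080 with TPM, 0.020 by library totals and -0.55 to 0.064 with each library left out. Pax7 was at 0.067 by library totals and -1.15 to 0.24 with each library left out.

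List medians in p16-null DMD against DMD with each library left out ranged from 0.028 to 0.21 for matrix, -0.59 to 0.0071 for interferon response and -0.18 to 0.045 for complement. The calls of Myod1, Cdkn1b and Aqp1 in DMD against WT ended with TPM and by library totals, and those of Nr1d1 (-0.51, adjusted p = 0.051) and Sesn1 (-0.46, adjusted p = 0.12) with TPM. That of Il6 in p16-null DMD against WT ended with TPM and a pseudocount of 1 (adjusted p = 0.056). With age the calls of Tgfb2 (adjusted p = 0.11), Ccn2 (0.22), Tgfb1 (0.15), Cd68 (0.14) and Actn3 (0.13) ended in the fit of 18 libraries, and those of Tgfb2 (0.062) and Spp1 (0.086) in the robust fit.

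By library totals the calls of some lists ended. In DMD against WT these were neutrophils and mast cells (adjusted p = 0.13) and proliferation (0.20). In p16-null DMD against WT they were adipocytes and T, B and NK cells (0.086 each), neutrophils and mast cells (0.22) and interferon response (0.12), and with age adipocytes (0.071) and slow fibres (0.11).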

Other observations

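Sohlh2, a transcription factor of germ cells, belongs to none of the gene lists and was followed across groups only after the result was seen. It had 1 count over the WT libraries of 9 months and 1 over those of 3 months, against 763 in DMD, 1936 in p16-null DMD and 293 in WT muscle at 18 months. The ratios were 470 (84.1 to 18580) in DMD and 612 (110 to 24167) in p16-null DMD, each against WT at 9 months, and 289 (51.5 to 11450) at 18 against 3 months. Levels of Sohlh2 varied widely, with 3.91, 29.1 and 13.0 CPM in DMD replicates 1 to 3 and 3.41 to 40.5 CPM in p16-null DMD, and without DMD replicate 2 the fitted change in DMD fell from 8.43 to 7.56 (adjusted p = 0.0015). Dystrophic and old muscle thus share a transcript that was all but silent in the WT libraries of 3 and 9 months.

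Nr4a3, an exercise and stress response gene, was high in WT muscle of 9 months, with 64.3 ± 12.5 CPM, and stood at 3.45 ± 0.847 at 3 months and 4.22 ± 1.38 at 18 months. The libraries of 9 months and those of 3 and 18 months were fitted apart, and this difference was not tested.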
